A study of Mus musculus with 8 samples.

How the data were processed

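Chromatin immunoprecipitation with sequencing (ChIP-seq) was done with an Nrf2 antibody on muscle satellite cells freshly isolated from mouse hindlimb. Per the labels, the 8 libraries form 4 groups of 2: input chromatin and Nrf2 ChIP from Keap1-null cells, and the same from Nrf2-null cells, with the libraries of a group told apart by a bench number. The labels do not say whether the benches handled separate animals, so the spread between libraries may be technical. Reads were handled with Trim Galore 0.6.10, BWA 0.7.17, SAMtools 1.6 and MACS2 2.2.7.1 on build mm10, per the submitters' processing notes. The settings, the use of the input libraries and any exclusion of blacklisted regions are not given in the sources used here.

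The measurements were 2 lists of peaks deposited by the authors, 1 per genotype, each made by joining the 2 Nrf2 ChIP libraries of that genotype. The columns follow the layout of the irreproducible discovery rate (IDR) procedure, which scores how reproducibly a peak ranks in a pair of libraries; the version used is not given in the sources used here. Each peak carries the deposited IDR score and the deposited −log10 IDR, in which higher means more reproducible. It also carries the deposited −log10 p of enrichment from the authors' peak calling in each library, and the smaller of the 2. The columns for fold enrichment and q hold only a placeholder, so no fold is reported. The library columns do not name the bench and are called the first and the second library of a list. Values per peak are the authors' own and were used only to describe, rank and filter peaks, apart from the tests named as such below. The files hold no read totals, so the depth per library is unknown, and −log10 p rises with depth.

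Peaks were counted as shared when they overlapped a peak of the other list by at least 1 bp, and Keap1-null peaks without such a partner were called Keap1-null-only. Shared counts were set against 1000 random placements of the Nrf2-null peaks on the same chromosomes, beginning at position 3000001. Coordinates are 1-based mm10 positions. Gene positions came from a RefSeq gene table of the same assembly with 49550 genes, 21627 of them protein-coding, on the chromosomes with peaks. That table gives the start and end of each gene but no strand, exons or sequence. Distances were therefore measured from the summit to the nearer end of a gene, in place of the planned distance to a transcription start site, and exons, introns and untranslated regions were not told apart. The planned searches for antioxidant response elements and other motifs, and the comparison of peak strength by motif, need sequence and were not run.

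The 15 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover canonical Nrf2 antioxidant and detoxification targets, NADPH and pentose phosphate enzymes, iron and heme handling, Keap1-Nrf2 pathway regulators, proteasome subunits, muscle stem cell quiescence, myogenic and early activation, heat shock and unfolded protein response, autophagy and lysosome, ribosomal proteins, and markers of immune cells, endothelium, fibro-adipogenic progenitors, myofibres, and Schwann cells with pericytes. All 335 list entries were found in the gene table, and a gene may stand in more than 1 list. A gene was near a peak when a summit lay within 10 kb of either of its ends. List members were compared with all other protein-coding genes by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 15 lists. Locations of Keap1-null-only and Nrf2-null peaks were compared by a two-sided Fisher's exact test. Named genes are those nearest to the 20 Keap1-null-only peaks of lowest IDR, all list members near a Keap1-null-only peak, those at the first 10 Nrf2-null and the first 10 shared peaks, and the knocked-out genes Keap1 and Nfe2l2. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only. Peaks of a list come from the same 2 libraries and are not replicates.

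Alternatives were an IDR of at most 0.01, autosomes alone, overlap of 50% of both peaks, summits within 200 bp, peaks within 1000 bp, gene-end distances of 500 and 5000 bp, protein-coding ends alone, windows of 1, 5 and 50 kb, the nearest gene alone, and all Keap1-null peaks. Added after seeing the data were the removal of a peak cluster at the start of chromosome 9, an IDR of at most 0.01 in the Keap1-null list alone, the gene span plus 10 kb, and circular shifts of genome-ordered genes, which keep neighbouring genes together. Permutation and sign-flip tests used 100000 resamples. The list test was tested on simulated data with 363 peaks and 21627 genes: of 200 lists of 38 genes with 12 planted near peaks, 100% passed at an unadjusted 0.05, as did 3% of lists without planted peaks. Other list sizes, fewer planted genes and lists of neighbouring genes were not simulated. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.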

Results

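Nrf2, encoded by Nfe2l2, is a transcription factor that activates antioxidant and detoxification genes, and Keap1 is the adaptor protein that directs it to degradation. Nrf2 occupancy was profiled by ChIP-seq in satellite cells, the stem cells of skeletal muscle, freshly isolated from the hindlimb of Keap1-null and Nrf2-null mice. Each genotype had 2 Nrf2 ChIP libraries and 2 input libraries, 8 in all. The study's title names quiescence and early activation of muscle stem cells as its subject. The comparison of genotypes asks which regions were enriched with the Nrf2 antibody when Keap1 was absent and not when Nrf2 itself was absent. The series has no wild-type group, so the peaks do not show where Nrf2 binds in satellite cells that have Keap1. The peak lists held 469 peaks for Keap1-null and 151 for Nrf2-null cells, with median widths of 409 and 392 bp. Depth per library is unknown.

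The knocked-out genes were examined first. A Keap1-null-only peak lay at Nfe2l2 itself (chromosome 2, 75703717 to 75704211), inside the gene and 696 bp from its end, with −log10 p of 16.2 and 9.39 in the first and second library and an IDR of 0.0122. The nearest Nrf2-null peak was 11954 kb from Nfe2l2. The labels do not say which part of the gene was deleted, so the missing peak checks neither the label nor binding there. Keap1 had no peak near it in either list, the nearest Keap1-null-only peak being 6193 kb away and the nearest Nrf2-null peak 1654 kb.

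Most Keap1-null peaks had no counterpart in the Nrf2-null list, whereas most Nrf2-null peaks had one in the Keap1-null list. Of the 469 Keap1-null peaks, 106 were shared (22.6%, 95% interval 18.9 to 26.7) and 363 were Keap1-null-only. Of the 151 Nrf2-null peaks, 102 were shared (67.5%, 95% interval 59.5 to 74.9) and 49 were not. Overlaps were almost pairwise, so a list of 151 peaks could not have given most of 469 peaks a counterpart. The share of Keap1-null peaks without a counterpart is thus partly set by the lengths of the lists. Random placement gave a mean of 0.043 shared peaks and at most 3 in 1000 placements. The shared share was 15.8% without a cluster of peaks at the start of chromosome 9, described with the shared peaks, and the Keap1-null list fell to 261 peaks at an IDR of at most 0.01.

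The strongest Keap1-null-only peaks included those at Esd, Txnrd1, Srxn1, Txn1, Slc7a11 and Nqo1. The 5 peaks at the lowest IDR listed, 1e-05, were tied and are ordered by the smaller −log10 p. The first in that order was inside Esd, which encodes esterase D (chromosome 14, 74733204 to 74733844), with −log10 p of 83.4 and 84.9. The next was inside Txnrd1, the cytosolic thioredoxin reductase (chromosome 10, 82858655 to 82859435), at 131 and 74.3; its nearest protein-coding gene end was that of Eid3, 7.50 kb away. Srxn1, which encodes sulfiredoxin, had a peak 126 bp from its end (chromosome 2, 152105043 to 152105940) at 85.0 and 62.2. Txn1, encoding thioredoxin, had a peak 482 bp from its end (chromosome 4, 57956530 to 57957223) at 54.8 and 49.3. Slc7a11, the cystine-glutamate antiporter, held a peak well inside the gene (chromosome 3, 50437879 to 50438536) at 63.2 and 47.4. Nqo1, encoding a quinone reductase, had a peak 411 bp from its end (chromosome 8, 107403316 to 107403868) at 67.5 and 38.3, and Pgd, an enzyme of the pentose phosphate pathway, had a peak 4.16 kb from its end at 49.9 and 30.9.

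The other peaks among these 20 were named by their nearest protein-coding gene end. Panx1, Rxra, Arhgap20, Reep3, Itsn1 and Lrp8 held the summit inside the gene. Summits outside genes lay 71.5 kb from Zfp36l2, 33.1 kb from Txn2, 18.4 kb from Hcfc2, 38.0 kb from Vegfa, 35.3 kb from Gm41291, 30.7 kb from Bcas1 and 109 kb from Tent4a. The peak nearest to Hcfc2 was also 19.7 kb from Txnrd1. In all, 9 of the 20 summits were inside a protein-coding gene and 9 were within 10 kb of a protein-coding gene end. Nearness does not show which gene a peak acts on.

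Canonical Nrf2 targets stood near Keap1-null-only peaks far more often than other genes did. Of 38 members, 16 had a summit within 10 kb (42.1%, 95% interval 26.3 to 59.2), against 0.783% of the other protein-coding genes (adjusted p = 1.2e-22, one-sided Fisher's exact test). They were Abcc1, Aox1, Cbr3, Ephx1, Gclc, Gclm, Gsr, Gsta1, Gsta2, Gstp1, Gstp2, Hmox1, Nqo1, Prdx1, Srxn1 and Txn1. Gclc and Gclm, the subunits of the enzyme that limits glutathione synthesis, differed in strength: the Gclc peak had −log10 p of 31.2 and 18.4 with an IDR of 0.00100, and the Gclm peak 8.07 and 11.1 with an IDR of 0.0496, near the end of the list. Cbr3, a carbonyl reductase, had a peak 704 bp from its end at 36.6 and 14.9, and Aox1, aldehyde oxidase, 85 bp from its end at 30.4 and 11.4. Gstp1 and Gstp2, neighbouring glutathione transferase genes, shared a peak. No member had an Nrf2-null peak within 10 kb, and 17 of the 363 Keap1-null-only peaks were near a member against 0 of 151 Nrf2-null peaks (p = 0.00470, two-sided Fisher's exact test). The chromosome 9 cluster holds 39 of these 151 peaks, which lie together and are not separate trials. Without that cluster, 17 of 363 stood against 0 of 112 (p = 0.0167, two-sided Fisher's exact test).

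Members of the iron and heme list and of the NADPH and pentose phosphate list were also near Keap1-null-only peaks more often than other genes. Of 11 iron and heme genes, 5 were near a Keap1-null-only peak (adjusted p = 1.44e-07, one-sided Fisher's exact test): the ferritin subunits Fth1 and Ftl1, the heme oxygenase Hmox1, the biliverdin reductase Blvrb and the heme transporter Slc48a1. The Fth1 peak lay 1.96 kb from the gene at 31.4 and 26.8. The Ftl1 peak, 1.10 kb from the gene at 39.8 and 19.4, lay closer to Bax, at 709 bp. Of 11 NADPH and pentose phosphate genes, 3 were near a peak (adjusted p = 4.83e-04, one-sided Fisher's exact test): Pgd, the transaldolase Taldo1 and the glucose-6-phosphate dehydrogenase G6pdx. Within 1 kb the iron and heme list had 0 members and the NADPH list 1 (adjusted p = 0.113, one-sided Fisher's exact test).

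Smaller groups of proteasome and pathway genes were also near peaks. Of 32 proteasome subunits, 3 were near a Keap1-null-only peak (adjusted p = 0.00954, one-sided Fisher's exact test), namely Psmb3, Psmd1 and Psmd3, with summits 168, 230 and 4 bp from the gene end. Of 14 Keap1-Nrf2 pathway regulators, 2 were, Nfe2l2 and Mafg, a small Maf partner of Nrf2 (adjusted p = 0.0186, one-sided Fisher's exact test). The proteasome call was lost with a 50 kb window (adjusted p = 0.238) and at an IDR of at most 0.01 (adjusted p = 0.392), by the same exact test. The regulator call was lost under both and with a 1 kb window (adjusted p = 0.238, 0.254 and 0.113, exact test). No member of the proteasome, regulator, iron and heme, or NADPH lists had an Nrf2-null peak within 10 kb. For Nfe2l2, the gene knocked out in the Nrf2-null cells, that absence cannot be read, since the deleted part is not known. For these lists the shares of Keap1-null-only and Nrf2-null peaks near a member were not compared by a test.

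**Figure D1:**
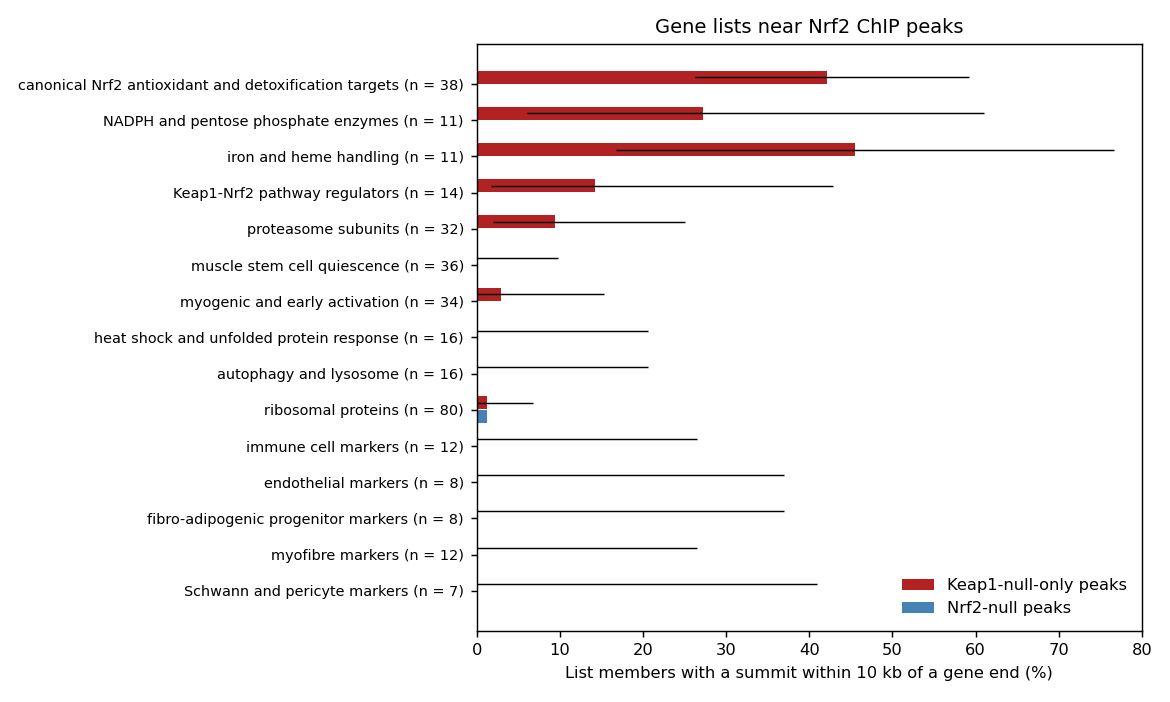
Share of the members of each gene list (percent, x axis) with a peak summit within 10 kb of a gene end, for Keap1-null-only peaks (red, with exact 95% intervals as lines) and Nrf2-null peaks (blue, no interval drawn). Canonical Nrf2 targets reached 42.1% and iron and heme genes 45.5%, and the Nrf2-null bar is above 0 only for ribosomal proteins, at 1 gene of 80.

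Genes of muscle stem cell state were not near the peaks more often than other genes. Of 36 quiescence genes, 0 had a Keap1-null-only summit within 10 kb (adjusted p = 1, one-sided Fisher's exact test). The closest was Sdc4, a satellite cell surface proteoglycan, at 37.9 kb, and the peak closest to Pax7, the defining transcription factor of these cells, was 1726 kb away. Of 34 myogenic and early activation genes, 1 was near (adjusted p = 0.634, one-sided Fisher's exact test): Fosl1, an AP-1 subunit, with a summit 1.12 kb from its end at −log10 p of 15.7 and 14.8. Myod1, a myogenic transcription factor, was 55.0 kb from its nearest peak. The 95% interval for the quiescence list reaches 9.74%, and a distal site would not be counted by a 10 kb window.

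No excess was called for other gene groups or for the markers of other cell types, but small lists had little power to show one. Heat shock and autophagy genes, with 16 members each, had 0 near a Keap1-null-only peak. Of 80 ribosomal protein genes, which mark highly transcribed promoters, Rps15a alone was near such a peak (adjusted p = 1, one-sided Fisher's exact test), and Rps29 alone was near an Nrf2-null peak. The markers of immune cells (12 genes), endothelium (8), fibro-adipogenic progenitors (8), myofibres (12), and Schwann cells and pericytes (7) gave 0 of 47 near Keap1-null-only peaks and 0 of 47 near Nrf2-null peaks. Of the 15 lists, 5 passed for Keap1-null-only peaks. For Nrf2-null peaks 0 passed, also at an unadjusted p under 0.05 (Fisher's exact test). Nrf2-null peaks lay within 10 kb of only 38 of 21627 protein-coding genes, against 185 for Keap1-null-only peaks. A count of 0 was thus likely for every list, and the lack of passing lists is no contrast between genotypes.

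The first 10 peaks of the Nrf2-null list were all shared with the Keap1-null list, and 8 of them lay over 10 kb from a protein-coding gene end. Its first peak (chromosome 17, 4626046 to 4626706) had −log10 p of 225 and 410 and lay 368 kb from Arid1b; in the Keap1-null list it had 369 and 353. The next was on chromosome 6 (132463554 to 132463995), 99.6 kb from Gm8882, at 71.2 and 78.4 in Nrf2-null and 72.4 and 77.4 in Keap1-null. Further leading Nrf2-null peaks were named by Gm45871, Tmem196, Pla2r1 and Dpp9, and 4 of the first 10 lay in a cluster near the start of chromosome 9, 311 to 331 kb from Alkbh8. The leading shared peaks in the Keap1-null order also included those named by Pex2, Acacb and Mrgprd. The chromosome 9 cluster, in the first 40 kb of the assembled sequence, held 39 Nrf2-null peaks, 38 shared Keap1-null peaks and 0 Keap1-null-only peaks. Shared peaks also covered the 7S RNA genes Rn7s1 and Rn7s2, with Rn7s1 beside Rps29, and the ribosomal RNA pseudogene Rn18s-rs5.

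**Figure D2:**
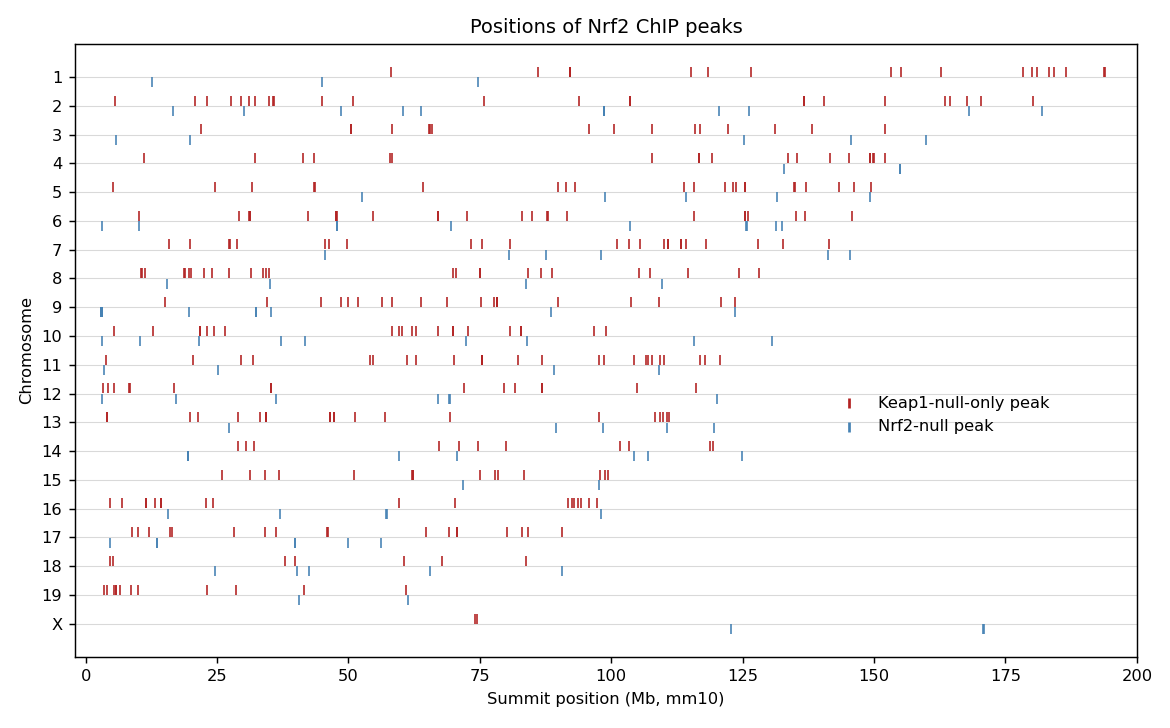
Summit positions (Mb, mm10, x axis) of Keap1-null-only peaks (red ticks) and Nrf2-null peaks (blue ticks) along each chromosome (y axis). The 363 Keap1-null-only peaks are spread over the chromosomes, and 39 of the 151 Nrf2-null peaks fall together at the start of chromosome 9.

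Keap1-null-only peaks were closer to genes than Nrf2-null peaks. A summit inside a protein-coding gene was found for 175 of 363 Keap1-null-only peaks (48.2%, 95% interval 43.0 to 53.5) and 36 of 151 Nrf2-null peaks (23.8%, 95% interval 17.3 to 31.4; p = 2.51e-07, two-sided Fisher's exact test). The median distance to a protein-coding gene end was 17.7 kb and 103 kb, the latter falling to 33.0 kb without the chromosome 9 cluster. Within 1000 bp of any gene end lay 57 of 363 (15.7%) and 11 of 151 (7.28%; p = 0.00989, two-sided Fisher's exact test), a difference of 8.42 percentage points that was 22.4 points within 5000 bp (p = 1.12e-06). Without the chromosome 9 cluster the difference within 1000 bp no longer passed (6.77 percentage points, p = 0.0870, exact test). The share inside genes still differed (48.2% against 32.1%, p = 0.00323, exact test). The 5000 bp distance was not run without the cluster.

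The values of the libraries were compared across the listed peaks, which are not independent replicates. The lists keep peaks that ranked alike in both libraries, so these correlations cannot show how well the libraries agreed. Spearman's rank correlation between the first and second library was 0.575 for all Keap1-null peaks and 0.715 for Nrf2-null peaks, with Pearson's r of 0.884 and 0.876. The rank correlation was 0.566 for the Keap1-null-only and 0.720 for the shared peaks of the Keap1-null list, and 0.35 for the 49 peaks of the Nrf2-null list alone. Peaks such as those at Srxn1, Txn1 and Nqo1 were stronger in the first library, as were 296 of the 363 Keap1-null-only peaks (81.5%, 95% interval 77.2 to 85.4), against 46 of 106 shared peaks (43.4%, 95% interval 33.8 to 53.4).

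**Figure D3:**
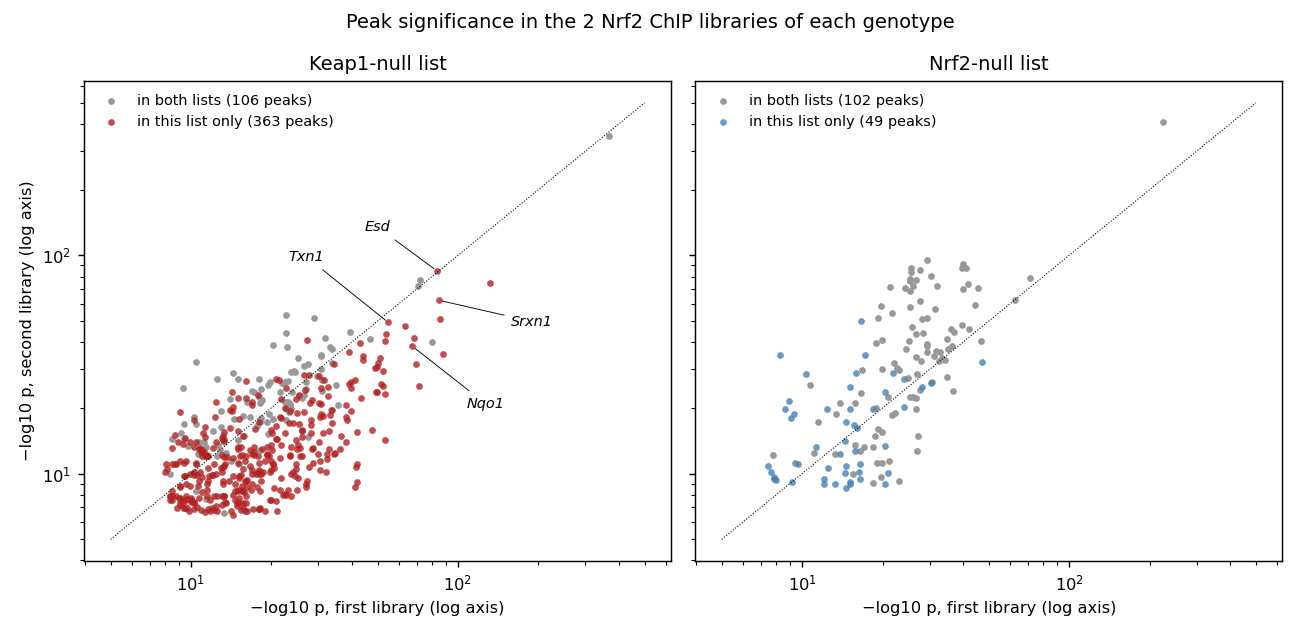
The authors' −log10 p of each peak in the first (x axis) and second (y axis) Nrf2 ChIP library, on log axes, for the Keap1-null list (left) and the Nrf2-null list (right); coloured points are peaks of that list alone, grey points are in both lists, and the dotted line marks equal values. In the left panel most coloured points, 296 of 363, lie on the side of the first library, while the grey points lie on both sides.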

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

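The alternatives without the chromosome 9 cluster, with a strict IDR in the Keap1-null list alone, with the gene span and with circular shifts were chosen after seeing the data. At an IDR of at most 0.01 the Keap1-null list held 261 peaks, 29.1% of them shared, and 185 were Keap1-null-only, or 182 with the limit on the Keap1-null list alone; fewer peaks follow from the limit itself. Without the cluster 15.8% were shared, and the median distance of Nrf2-null peaks to a protein-coding gene end was 33.0 kb. The gene-end difference within 1000 bp was then 6.77 points and did not pass (p = 0.0870, two-sided Fisher's exact test). The number of lists passing, 5, became 2 with a 1 kb window, 3 with 50 kb and 3 at the strict IDR; iron and heme genes had 0 members within 1 kb, their nearest peaks lying 1.10 kb or more from the gene. The canonical targets passed under all 8 alternatives to their test (adjusted p from 2.93e-23 to 0.000231, Fisher's exact test or circular shifts). The 0.000231 came from circular shifts, whose unadjusted p of 4.62e-05 is the smallest they can give, so it does not measure weaker evidence. The other overlap rules and autosomes moved no count of peaks by over 1.5 times. No gene-end distance ended a location call; within 5000 bp of a gene end lay 156 Keap1-null-only and 31 Nrf2-null peaks, a difference of 22.4 points. No paired analysis was possible because each list combines both libraries of a genotype and its library columns do not name the bench. Leaving out each replicate was not run for the same reason: a peak needs both libraries. Settings for antioxidant response elements, motifs and fold enrichment, set out beforehand, were not run, lacking sequence and fold values. Unknown depth limits any reading of absent peaks, since the lists hold only peaks that passed.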

Other observations

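All tests in this part were chosen after the results they concern had been seen. Outside the gene lists, Keap1-null-only peaks lay 175 bp from the proteasome subunit gene Adrm1 and 1.16 kb from the proteasome assembly chaperone Psmd5. Peaks also lay 451 bp from the glycogen branching enzyme gene Gbe1, with −log10 p of 51.6 and 25.6 in the first and second library, 4.75 kb from catalase (Cat), at 30.2 and 28.0, 5.50 kb from Aldh3a1 and 6.24 kb from Slc3a2, the partner subunit of Slc7a11. These genes were picked after their values were seen, and no theme was tested on them. Slc7a11 and Txnrd1 held peaks inside the gene but over 10 kb from its ends, so 18 of the 38 canonical targets had a peak when the gene span was counted.

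Peaks near canonical targets were stronger than other Keap1-null-only peaks, with a median smaller −log10 p of 15.8 for 17 peaks and 10.8 for 346 (p = 0.00467, two-sided permutation test across peaks). Quiescence genes were a median of 2010 kb from the nearest Keap1-null-only peak and activation genes 1199 kb, against 2065 kb for all protein-coding genes. These medians stood at the 46.7 and 6.56 percentile of 10000 random lists of the same size, so neither list was shown to lie closer to, or farther from, the peaks than other genes.

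The absence of Nrf2-null peaks at Srxn1, Nqo1 and the other targets could come from lower sequencing depth in the Nrf2-null libraries alone. Only 3 of the 17 peaks near canonical targets are among the 20 leading Keap1-null-only peaks, and the rest are among the other 343. For the 20 leading peaks the values argue against depth alone. It would have to cut the smaller −log10 p to 25.3% or less to reach the lowest Nrf2-null value listed, 7.45. The 9 shared peaks outside the chromosome 9 cluster that were as strong in Keap1-null kept a median of 88.3% and at least 47.1%. At 25.3% the weaker of these 9 would lie close to the lowest value listed, so a larger fall could go unseen. The strongest of them had room to fall further and stay listed, yet had 225 in Nrf2-null against 353 in Keap1-null, 71.2 against 72.4 and 62.5 against 70.8. For the other 343 peaks lower depth cannot be told apart: shared peaks outside the cluster were higher in Nrf2-null by a median of 4.25, in 48 of 68 (p = 1e-05, the smallest the sign-flip permutation test can give), but weak shared peaks are listed only where they stayed high enough, and 4 of the 10 strongest over both lists were higher. A lower yield of the Nrf2-null immunoprecipitations stays open for all of them. Occupancy of the targets by Nrf2, the difference the design names, also stays open, with no test here beyond the comparison in the results.

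Shared peaks, present without Nrf2, might mark another protein that the antibody recognises at Nrf2 target genes. For the 38 canonical targets the listed peaks argue against this, as 0 of 151 Nrf2-null peaks lay near a member. Without the chromosome 9 cluster the count was 0 of 112. Weaker signal at these genes that was not listed cannot be seen, and a lower yield of the Nrf2-null immunoprecipitations might hide it. The 0 of 106 shared peaks, against 17 of 363 Keap1-null-only peaks (p = 0.0171, two-sided Fisher's exact test), restate that observation and are not separate evidence. Other Nrf2 target genes were not covered, as 346 of the 363 Keap1-null-only peaks were near no member. Multi-copy sequence assembled at a few places is another candidate explanation: 38.7% of shared peaks (95% interval 29.4 to 48.6) lay in the chromosome 9 cluster or over Rn7s1, Rn7s2 or Rn18s-rs5. Of the 41 peaks in that share, 38 lay side by side in the cluster, so the interval counts the same locus many times. Multi-copy sequence and other sources of signal cannot be told apart for the other 65 shared peaks, because no sequence was used here. Binding of another protein away from the target genes was not tested.

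The first Keap1-null library had the larger −log10 p at most Keap1-null-only peaks, and greater depth alone might produce this. Depth alone would raise shared peaks too, yet the first library led at 43.4% of those against 81.5% of Keap1-null-only peaks (p = 1.29e-13, two-sided Fisher's exact test across peaks). The lowest values listed, 8.0 in the first and 6.5 in the second library, might shift weak peaks, but among peaks with a geometric mean of at least 20.2 the first library still led at 79 of 89 Keap1-null-only and 24 of 53 shared peaks (p = 4.12e-08, same exact test). A difference between the libraries in immunoprecipitation yield stays open, and no biological explanation was tested. Both libraries have the same genotype, but a difference between animals or cell preparations also stays open, since the labels do not say whether the animals were separate.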
